A study of Sus scrofa with 24 samples.

How the data were processed

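Small RNA libraries were sequenced from porcine alveolar macrophages (PAMs), the resident macrophages of the lung and the main target cell of porcine reproductive and respiratory syndrome virus (PRRSV). The cells were obtained by lung lavage from young specific-pathogen-free pigs of 4 breeds (Landrace, Meishan, Pietrain and QingPing) and were kept in culture with or without PRRSV for 9, 36 or 60 h. The labels give 1 library for each combination of breed, infection state and time, 24 libraries in all. Each of the 6 infection and time groups therefore held 4 libraries, 1 per breed, and each breed held 6 libraries. The labels do not say whether the libraries of a breed came from the same animals or from a pool, so p-values measure the spread between these libraries, which may be technical.

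Per the file headers, the authors deposited 60 pairwise tables and 1 table of uninfected 9 h libraries, in which the Pietrain column carries the name of the infected 9 h library; the column was assigned by its name. The deposited tables give counts (reads per miRNA), the library total of clean reads, and normalised values whose unit was found to be reads scaled to the library total (rpm, per 1e6 clean reads), although the authors named the files for another unit that includes a length. Division of each count by its library total returned the deposited rpm value to within 5e-05. The authors also deposited log2 fold changes between 2 libraries, p values (p_value) of 1 library against another, and other columns such as significance marks and sequences. The authors wrote a value of 0 as 0.01, and a miRNA was listed in a pairwise table when at least 1 of its 2 libraries was above 1 rpm. The aligner, the genome build and the miRNA database version are not given in the sources used here. The significance marks were displaced in 30 of 60 tables and were not used, and 361 unlabelled entries in 3 tables were left out.

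Counts were joined over all tables by library and miRNA. Of the cells given in at least 2 tables, 8711 held a count, and 0 of these differed. A further 98 counts were obtained from the rpm value and the library total. The remaining 1579 of the cells for 265 miRNAs and 24 libraries (24.8%) were not listed and were taken as 0. Among the miRNAs tested this share was 2.6%. By the listing rule an unlisted value may lie anywhere up to about 1 rpm. The table of 9 h libraries listed every miRNA for the Landrace, Meishan and QingPing uninfected and the Pietrain infected library, so that low values were visible in these 4 libraries and not in the others. For 2 Meishan libraries (infected 9 h and uninfected 60 h) the tables held 2 differing sets of values under 1 name. These sets were read as sequencing runs and are called runs here, which the values alone do not show. The run with counts, called run 1, was used, and run 2 was used as an alternative after its library total had been recovered from the smallest step between its rpm values. The miRNA miR-223, one of 7 that were to be named whatever their value, was not analysed here.

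The clean reads per library ranged from 12.3 to 16.6 M (1 M is 1e6 reads) and the miRNA reads from 3.91 to 11.65 M. A count of 3 reads, taken as the floor that a listed count of 0 allows, was 0.181 to 0.243 rpm; an unlisted value allows up to about 1 rpm. Such floors cover counting error only, because reads amplified by PCR without molecular identifiers are not independent molecules. No pair of libraries had counts that agreed within sampling noise (smallest chi-square per degree of freedom 91.6), so none was merged. This finds only a library deposited more than once, and it does not show that libraries came from different RNA, since separate preparations of 1 RNA also differ by more than sampling noise.

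miRNAs with at least 10 reads in at least 4 libraries were tested, which left 186 of 265 miRNAs and 99.99% of the miRNA reads. Because counts were present, the tests used edgeR 4.0.16 in R 4.3.3 (quasi-likelihood fit, TMM factors on the clean-read totals, robust estimation off), as laid down before the data were examined for that case. The model held the mean of each of the 6 infection and time groups plus breed as a term (15 residual degrees of freedom). Contrasts compared infected with uninfected cells over all times and at 9, 36 and 60 h, the infection effects between times, the times within each infection state, and the breeds. A model with a term for the infection effect of each breed (12 residual degrees of freedom) tested whether that effect differed between breeds. p-values were adjusted by the Benjamini-Hochberg method over the 186 miRNAs of a contrast, and an adjusted p below 0.05 was required. Libraries of 1 breed deviated together from their group means (median correlation across miRNAs 0.47 against -0.12 between breeds), which the breed term removes. The joining of the tables and the figures used Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9. Values are given as rpm after TMM scaling, as mean ± SD, and log2 fold changes as fitted by edgeR with their standard error (SE).

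The miRNAs named were chosen by a rule written before the data were examined. It took up to 10 miRNAs per direction with the largest change among those past the threshold and moved the same way in 4 of 4 breeds (10 of 12 pairs over all times). For the breed test and the interactions it took the 12 with the smallest p. Where fewer than 5 passed it took the 5 with the smallest p, and it added up to 4 passing members of each list. A set of 7 macrophage and PRRSV-related miRNAs was to be named in every comparison, of which 6 were found. The single-library values of miR-142-5p, miR-146b, miR-31 and miR-10a-5p in the Landrace uninfected 9 h library, and of miR-1, were chosen after the values were seen. So were the group means that the text prints.

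Before the data were examined, 15 lists were fixed: inflammation-induced miRNAs of macrophages, miRNAs with a reported action on PRRSV, myeloid and pan-leukocyte miRNAs, the let-7, miR-17-92, miR-30, miR-29, miR-15/16 and miR-181 families, hypoxia, p53 and stress miRNAs, the imprinted DLK1-DIO3 cluster, and markers of epithelial cells, erythrocytes, lymphocytes, and endothelial, fibroblast and muscle cells. The DLK1-DIO3 list had 0 tested members. Lists with at least 5 tested members were compared with the other miRNAs by camera (limma 3.58.1) with a preset correlation of 0.01, and with the correlation estimated as an alternative.

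The procedure was tested on simulated data in which 40 of the 186 miRNAs were changed. For infection at 9 h it recovered 1.5% of 2-fold and 51.2% of 4-fold changes. For infection over all times it recovered 37.2% and 89.2%, and for breed 1.8% and 74.2%. For the infection effects between breeds it recovered 0% and 0.8%. The alternatives were DESeq2 1.42.0 in place of edgeR, upper quartile and DESeq2 size factor scaling, no filter, a minimum of 100 reads, only miRNAs listed in every library, miRNAs of identical values counted once, no breed term, each breed or group left out, and fits of single times or infection states. Alternatives chosen after the data were seen left out libraries that stood apart, used run 2, or scaled by the clean reads alone. Others used TMM on the sum of the tested miRNA reads, set edgeR's robust option, set unlisted values to 1 rpm, or took every value under 1 rpm as 0. Libraries were said to stand apart when the median Spearman correlation with the other libraries was under 0.87 or the miRNA reads were under 50% of the clean reads; both limits were set after these values were seen.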

Results

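The data held 24 small RNA libraries of PAMs, with 4 libraries, 1 per breed, in each of 6 groups: uninfected and PRRSV-infected cells at 9, 36 and 60 h. The miRNA reads per library ranged from 3.91 to 11.65 M (1 M is 1e6 reads), and 186 miRNAs were tested. In 20 libraries the miRNAs made up 60.0% to 74.6% of the clean reads, and the median Spearman correlation with the other libraries across miRNAs was 0.909 to 0.957. The other 4 stood apart on at least 1 of these measures.

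**Figure D1:**
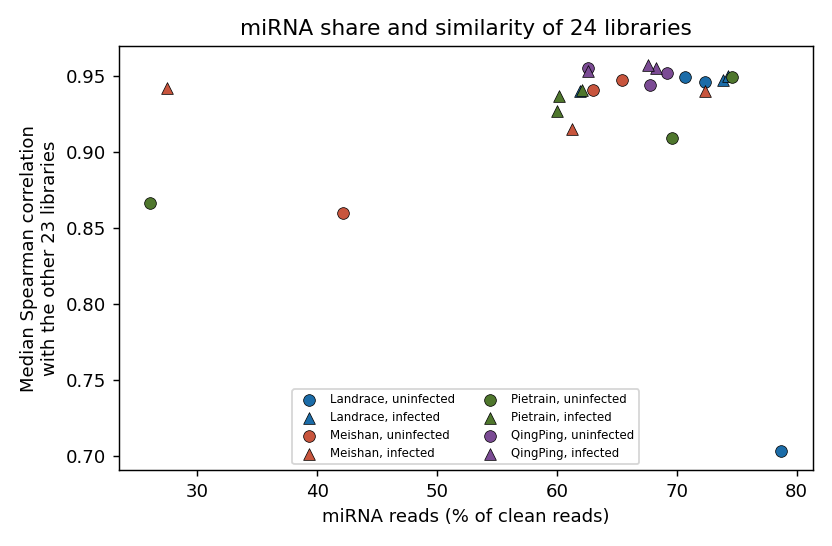
Each point is 1 of the 24 libraries, with the percent of clean reads assigned to miRNAs on the horizontal axis and the median Spearman correlation with the other libraries on the vertical axis; colours mark breeds, circles uninfected and triangles infected cells. The Landrace uninfected 9 h library has the lowest correlation (0.703), and the Pietrain uninfected 9 h library the lowest miRNA share (26.1%).

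The libraries that stood apart were Landrace uninfected 9 h, Pietrain uninfected 9 h, Meishan uninfected 60 h and Meishan infected 9 h. In the Landrace uninfected 9 h library, miR-142-5p, a miRNA of blood-derived cells, was at 2.55 rpm against 1361 ± 393 rpm (SD, n = 5) in the other Landrace libraries. In the same library miR-146b, which inflammatory signals induce in macrophages, was at 37.2 rpm, and it was between 18994 and 31407 rpm in the other Landrace libraries. miR-31 reached 791.5 rpm, miR-10a-5p 2499 rpm and miR-92b-5p 1646 rpm there. Its median correlation with the other libraries was 0.703. The Pietrain uninfected 9 h library had a correlation of 0.866 and a miRNA share of 26.1%, the Meishan uninfected 60 h library 0.860 and 42.2%, and the Meishan infected 9 h library 0.942 and 27.5%.

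**Figure D2:**
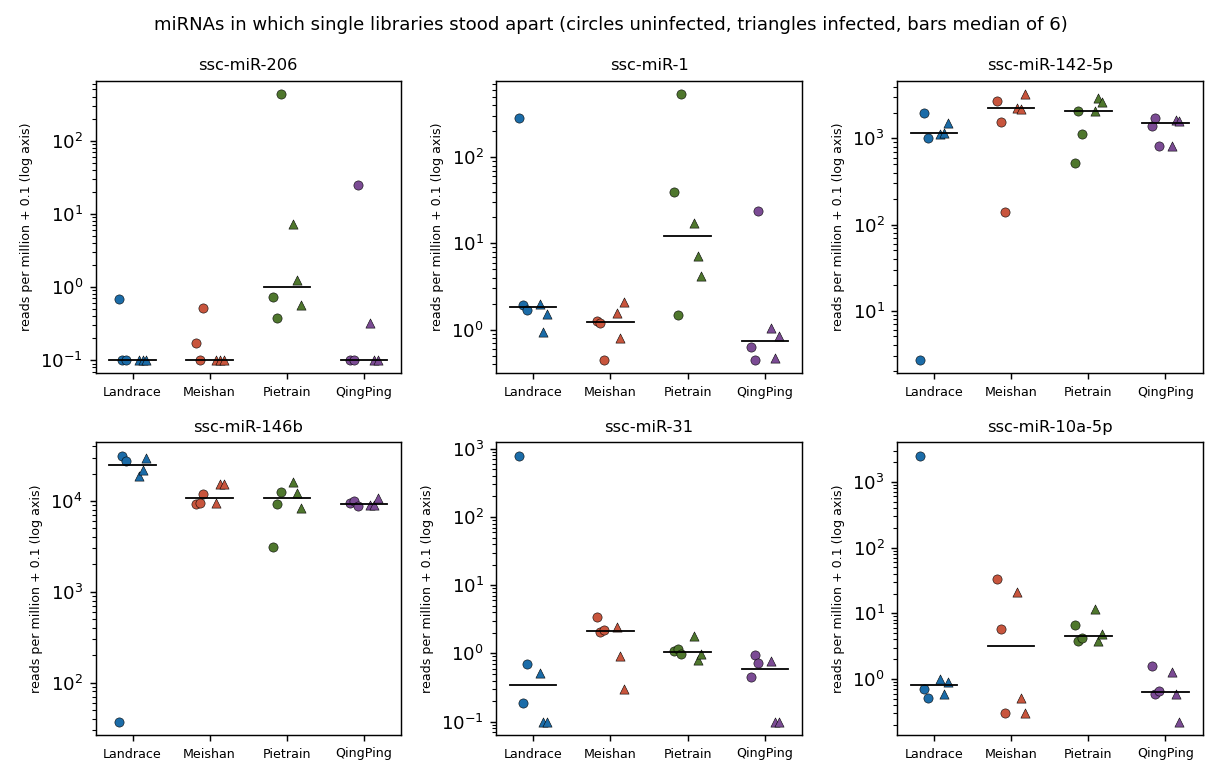
Each point is 1 library, in rpm after TMM scaling plus 0.1 on a log axis, for 6 miRNAs in which single libraries lay apart; circles are uninfected, triangles infected cells, and bars are the median of the 6 libraries of a breed. The Landrace uninfected 9 h library is at 2.55 rpm for miR-142-5p, and the Pietrain uninfected 60 h library is at 428.9 rpm for miR-206.

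The first question was how PRRSV infection changed the miRNAs of PAMs over all 3 times. The smallest p-values belonged to miR-92b-5p, miR-1307, miR-320, miR-769-3p and miR-31. Their fitted log2 differences between infected and uninfected cells were -2.33 (SE 0.68) for miR-92b-5p, -1.45 (SE 0.44) for miR-1307, -0.87 (SE 0.27) for miR-320, -1.31 (SE 0.42) for miR-769-3p and -3.70 (SE 1.19) for miR-31, and none passed the test. Without the Landrace uninfected 9 h library, where miR-31 was at 791.5 rpm, the difference was -1.36 for miR-31 and -1.20 for miR-92b-5p, and without the Meishan uninfected 60 h library it was -0.93 for miR-1307 and -0.58 for miR-320. For miR-31 it was -2.30 with unlisted values set to 1 rpm. miR-92b-5p, miR-320 and miR-31 were lower in 10 of 12 infected libraries than in their uninfected partners. miR-146a-5p, a feedback inhibitor of Toll-like receptor signalling, was higher in 10 of 12 pairs, with a log2 difference of 0.62 (SE 0.51), and miR-155-5p, a miRNA induced in activated macrophages, in 7 of 12, with 0.33 (SE 0.34), which turned to -0.22 without the 4 libraries that stood apart. The differences were 0.59 (SE 0.41) for miR-142-3p, 0.29 (SE 0.26) for miR-21, -0.50 (SE 0.40) for miR-181a and -0.13 (SE 0.20) for miR-30c-5p. In edgeR 0 of 186 miRNAs passed (smallest adjusted p 0.177), while 28 had an unadjusted p below 0.05, 5 higher and 23 lower; DESeq2 called 13, all lower. Adjusted over the list alone, 1 member of the miR-17-92 list (miR-92b-5p) and 2 members of the endothelial, fibroblast and muscle list (miR-1 and miR-206) passed, all lower. None of these 3 did without the 4 libraries that stood apart. In that fit miR-181c (-0.54) and miR-181d-5p (-0.6) passed over the miR-181 list alone, both lower. Without the Landrace uninfected 9 h library only, miR-181a (-0.79), miR-181c (-0.59) and miR-181d-5p (-0.67) passed over it. miR-222 (-0.72), miR-92a (-0.78), miR-92b-5p (-1.20) and miR-19a (2.81) passed over their lists in that fit. miR-19a was not listed in any uninfected 60 h library. With all libraries 4 of 4 miR-181 miRNAs were lower and 0 passed.

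At 9 h the comparison addressed the early phase of infection. miR-92b-5p was lower in the infected library of 4 of 4 breeds, at 7.05 ± 5.91 rpm (SD, n = 4) against 425 ± 814 rpm (SD, n = 4), a mean set by 1646 rpm in the Landrace uninfected library. miR-142-3p, the partner strand of miR-142-5p, was higher in 4 of 4 breeds, at 44.8 ± 11 rpm against 15.4 ± 17.7 rpm (SD, n = 4 each), with a log2 difference of 1.77 (SE 0.74). miR-155-5p was at 112 ± 77.4 rpm in infected and 42.5 ± 25.96 rpm in uninfected cells (SD, n = 4 each), higher in 3 of 4 breeds, and its other strand, miR-155-3p, differed by 4.02 (SE 1.23) on the log2 scale. miR-92b-3p differed by -3.65 (SE 1.06), miR-139-3p by -3.68 (SE 1.13) and miR-100 by -5.83 (SE 1.94). With the Landrace uninfected 9 h library left out, the differences were -1.80 for miR-92b-5p, -1.18 for miR-92b-3p, -0.73 for miR-139-3p, -1.11 for miR-100, 1.16 for miR-142-3p and 0.76 for miR-155-5p. miR-100 was not listed in 2 of the 4 infected libraries, and with unlisted values set to 1 rpm its difference was -3.35. The differences were 0.72 (SE 0.45) for miR-21, -0.49 (SE 0.35) for miR-30c-5p, 0.75 (SE 0.89) for miR-146a-5p (0.21 without the same library) and -0.52 (SE 0.69) for miR-181a (0.27 without the Pietrain uninfected 9 h library). Without the 4 libraries that stood apart the direction turned for miR-100 (0.14), miR-155-5p (-0.08), miR-21 (-0.05), miR-30c-5p (0.11) and miR-146a-5p (-0.10). None of these passed the test: edgeR called 0 of 186 miRNAs (smallest adjusted p 0.161), 35 had an unadjusted p below 0.05 (8 higher, 27 lower), and DESeq2 called 17 (2 higher, 15 lower). Of the myeloid and pan-leukocyte miRNAs, 12 of 13 had a higher value in infected cells (11 of 13 when scaled by the clean reads alone), and the set was higher than the other miRNAs in the camera test (adjusted p = 0.0166 with the preset correlation, adjusted p = 0.41 with an estimated correlation). Without the Landrace uninfected 9 h library, in which miR-142-5p was at 2.55 rpm, 8 of 13 were higher and the set test gave an adjusted p of 0.414. Without the 4 libraries that stood apart the direction turned, with 5 higher and 8 lower, a median log2 difference of -0.03 and an adjusted p of 0.83. Adjusted over the list alone, 3 of 16 inflammation-induced miRNAs, 2 of 10 of the miR-17-92 list, 3 of 7 hypoxia, p53 and stress miRNAs, 1 of 3 epithelial and 1 of 5 lymphocyte miRNAs passed. Of the 3 inflammation-induced miRNAs 1 was higher, miR-155-3p (4.02), and 2 were lower, miR-125a (-1.65) and miR-99b (-2.24). Both of the miR-17-92 list were lower, 2 of the stress list were higher and 1 lower, and the epithelial and the lymphocyte miRNA were higher. The epithelial one was miR-34c, which is also 1 of the stress miRNAs counted here. The lymphocyte one was again miR-155-3p, so these 2 lists added no further miRNA. No member of these 5 lists passed without the Landrace uninfected 9 h library. In that fit let-7d-3p (-1.62) passed over the let-7 list alone, lower in infected cells.

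None of the 4 libraries that stood apart was at 36 h, and the test of infection by time called 0 of 186 miRNAs. Fewer small p-values at 36 h therefore do not show a smaller effect of infection. By edgeR, 1 miRNA had an unadjusted p below 0.05 at 36 h, the fewest of the 3 times. That miRNA was miR-218-3p, at 0.580 ± 0.408 rpm in infected and 0.162 ± 0.324 rpm in uninfected cells (SD, n = 4 each), but 3 of the 4 uninfected libraries did not list it, and with unlisted values set to 1 rpm its difference turned from 2.57 to -1.39. The next smallest p-values belonged to miR-139-5p, miR-19a, miR-4332 and miR-122, a liver miRNA, and none passed. miR-139-5p, miR-19a and miR-4332 turned direction in the same fit (-0.26, -0.85 and -0.22). miR-146a-5p was higher in 4 of 4 infected libraries, with a log2 difference of 0.44 (SE 0.86). The differences were -0.33 for miR-181a, 0.12 for miR-30c-5p, 0.14 for miR-21, 0.10 for miR-142-3p and -0.07 for miR-155-5p. Without the Landrace uninfected 9 h library they were -0.03 for miR-30c-5p, 0.00 for miR-21 and -0.07 for miR-142-3p. edgeR called 0 of 186 miRNAs (smallest adjusted p 1) and DESeq2 called 0.

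At 60 h, the late phase, miR-206, a miRNA known from skeletal muscle, was called as lower in infected cells. The call rested on how values under 1 rpm, listed or not, were read. miR-206 was at 113 ± 211 rpm in uninfected and 0.116 ± 0.233 rpm in infected cells (SD, n = 4 each). The uninfected mean rested on the Pietrain library at 428.9 rpm and the QingPing library at 24.3 rpm, with 0.411 rpm in Meishan and 0 in Landrace; of the infected libraries Pietrain was at 0.466 rpm and QingPing at 0, and Landrace and Meishan did not list it and were taken as 0. It was lower in 3 of 4 breeds (edgeR, adjusted p = 0.0096), and the fitted log2 difference of -9.35 (SE 1.82) depends on the prior count and on these values. With unlisted values set to 1 rpm the difference was -4.75 and the call ended (adjusted p = 0.494), and with every value under 1 rpm taken as 0 it was -13.45 and the call ended too (adjusted p = 0.106). miR-1, another muscle miRNA, chosen after its values were seen, was at 141 ± 264 rpm in uninfected and 2.06 ± 1.43 rpm in infected cells (SD, n = 4 each). The uninfected mean was set by the same Pietrain library, at 537.2 rpm. miR-222, which inflammatory signals regulate in macrophages, was lower in 4 of 4 infected libraries, at 1219 ± 834 rpm against 2093 ± 908 rpm (SD, n = 4 each), with a log2 difference of -0.95 (SE 0.33), and did not pass (adjusted p = 0.282). miR-1307 (-2.75, SE 0.83), miR-184 (5.95, SE 2.01) and miR-24-2-5p (3.71, SE 1.29) did not pass either. Setting unlisted values to 1 rpm turned miR-184 and miR-24-2-5p to -1.05 and -0.35, and without the Meishan uninfected 60 h library the difference of miR-1307 was -1.07. The differences of miR-181a (-0.67), miR-155-5p (-0.20), miR-142-3p (-0.09) and miR-30c-5p (-0.03) did not pass. miR-146a-5p was at 129 ± 65.8 rpm against 69.0 ± 30.7 rpm (SD, n = 4 each), higher in 4 of 4 breeds without passing, and miR-21 at 48580 ± 17870 rpm against 47020 ± 13930 rpm (SD, n = 4 each). The fitted difference of miR-21 was 0.02 and had no stable direction, with -0.21 under DESeq2 and -0.16 under scaling by the clean reads alone. edgeR called 1 of 186 miRNAs, 20 had an unadjusted p below 0.05, and DESeq2 called 9, of which 1 was miR-206. miR-206 belongs to the list of miRNAs with a reported action on PRRSV, of which 1 of 33 passed over all miRNAs and 1 adjusted over the list alone, and to the endothelial, fibroblast and muscle list, of which 1 of 6 passed over all and 2 adjusted over the list alone; 2 of 3 epithelial miRNAs, miR-182 and miR-183, passed adjusted over the list alone, both higher. In this list 0 of 3 passed without the 4 libraries that stood apart or under either other reading of values under 1 rpm. Without those 4 libraries miR-221-3p (-0.59) and miR-222 (-1.08) passed over the inflammation-induced list alone, both lower. The call of miR-206 ended without Meishan (log2 difference -9.66, adjusted p = 0.134), without QingPing (-8.66, adjusted p = 0.323), without Pietrain (-9.30, adjusted p = 0.357) and without the breed term (-9.79, adjusted p = 0.211), so that these fits lost the call with a difference of similar size. It kept an adjusted p of 0.0395 without the Pietrain uninfected 60 h library.

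Whether the infection effect differed between times was tested as an interaction. The smallest p-values belonged to miR-206, miR-184, miR-139-5p, miR-362 and miR-183, the last a miRNA of epithelial and sensory cells, and none passed. Between 60 h and 9 h the infection effect differed by -8.60 for miR-206 and by 9.60 for miR-184 on the log2 scale. The highest value of miR-184 in any library was 6.65 rpm, and with unlisted values set to 1 rpm the differences were -5.54 for miR-206 and 0.38 for miR-184. The differences were -1.86 for miR-142-3p, -1.45 for miR-155-5p, 0.47 for miR-30c-5p, -0.71 for miR-21, -0.15 for miR-181a and -0.09 for miR-146a-5p. The direction of the last 4 turned without the 4 libraries that stood apart (-0.46, 0.12, 0.29 and 0.33). It turned for miR-181a (0.22) and miR-146a-5p (0.46) without the Landrace uninfected 9 h library. edgeR called 0 of 186 miRNAs (smallest adjusted p 0.241), 15 had an unadjusted p below 0.05, and DESeq2 called 0. miR-206 passed without the Landrace uninfected 9 h library (adjusted p = 4.55e-05), as it did without the Landrace breed (adjusted p = 6.57e-05).

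The times were compared within each infection state to describe how the cells changed in culture. Within each state, 1 joint test asked whether any of the 3 times differed. The differences given are those of 60 h minus 9 h. In uninfected cells miR-139-5p, a miRNA lost in many tumours, was called as lower at later times: it was at 7.84 ± 13.6 rpm at 9 h and 0.0956 ± 0.191 rpm at 60 h (SD, n = 4 each; edgeR, adjusted p = 0.00712). At 60 h, 3 of the 4 libraries did not list it, while the 9 h table listed every miRNA for Landrace, Meishan and QingPing. With unlisted values set to 1 rpm the log2 difference was -2.35 (adjusted p = 0.285), and with every value under 1 rpm taken as 0 it was -9.29 (adjusted p = 0.307), so that the call depended on the listing. The 9 h mean was set by 28.2 rpm in the Landrace library that stood apart, and the other libraries were at 0.365 to 2.27 rpm. Without that library the call held, with an adjusted p of 0.00354 and a log2 difference of -3.77 in place of -6.25. miR-206 was called as well (edgeR, adjusted p = 0.0112). It was at 0.323 ± 0.333 rpm at 9 h and 113 ± 211 rpm at 60 h (SD, n = 4 each), higher at 60 h in 3 of 4 breeds. At 36 h, 3 of the 4 uninfected libraries did not list miR-206. In the single contrast of 60 h with 9 h, 0 of 6 endothelial, fibroblast and muscle miRNAs passed over all miRNAs, so miR-206 did not. In that contrast miR-206 passed without the Landrace uninfected 9 h library (edgeR, adjusted p = 5.17e-05) and without the 4 libraries that stood apart (0.000759). The log2 difference of miR-206, 5.06, was 8.71 without the Landrace uninfected 9 h library and 3.18 without the Pietrain uninfected 9 h library. Its call ended with unlisted values set to 1 rpm (6.66, adjusted p = 0.166) and with every value under 1 rpm taken as 0 (13.09, adjusted p = 0.053). Next came miR-184, miR-15b, a member of the miR-15/16 family of cell cycle regulators, and miR-10a-5p, all just short of the threshold (adjusted p = 0.0501 for each). miR-184 was not listed in any uninfected 60 h library, and with unlisted values set to 1 rpm its difference was -0.91 in place of -7.85. miR-15b and miR-10a-5p were lower at 60 h in 4 of 4 breeds; without the Landrace uninfected 9 h library miR-10a-5p differed by -2.91 in place of -8.91. The differences were -1.04 for miR-30c-5p, 1.15 for miR-21, 2.29 for miR-146a-5p, 1.64 for miR-142-3p, 0.92 for miR-155-5p and 0.02 for miR-181a, and none passed. edgeR called 2 of 186 miRNAs, 38 had an unadjusted p below 0.05, and DESeq2 called 25, of which 1 was shared. The inflammation-induced miRNAs were higher at 60 h than at 9 h in uninfected cells for 12 of 16 members (camera, adjusted p = 0.0218 with the preset correlation, adjusted p = 0.0678 with an estimated correlation), and without the Landrace uninfected 9 h library the set test gave an adjusted p of 0.0566, and without the 4 libraries that stood apart 0.323. The call of miR-139-5p ended without Meishan (-6.87), without QingPing (-6.79), without Pietrain (-9.10) and with the uninfected libraries fitted alone (-5.33), with differences of similar size or larger. The call of miR-206 ended in the same fits, at 5.87, 2.55, 3.18 and 6.20, those without QingPing and Pietrain below the 5.06 of all libraries.

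The fixed lists were also examined in the single contrast of 60 h with 9 h in uninfected cells, which has its own adjustment. Over all miRNAs miR-15b of the miR-15/16 list (1 of 8) and miR-10a-5p and miR-130a of the PRRSV list (2 of 33) passed, all lower at 60 h. None of these lists' members passed over all with either other reading of values under 1 rpm. miR-15b (-1.51, adjusted p = 0.109) and miR-10a-5p no longer passed over all without the Landrace uninfected 9 h library. miR-130a still did (-6.83, adjusted p = 0.0313). None of the 3 passed without the 4 libraries that stood apart. In that fit other list members passed over all, each higher at 60 h: miR-206 (9.11), miR-1 (5.65), let-7e (1.4) and miR-99b (1.72). With all libraries and adjusted over the list alone, 8 of 33 PRRSV, 5 of 10 miR-30, 3 of 10 miR-17-92 and 1 of 8 miR-15/16 miRNAs passed. So did 1 of 7 hypoxia, p53 and stress miRNAs, miR-210, which hypoxia induces and which is also 1 of the 8 PRRSV miRNAs. miR-30c-3p and miR-30c-5p were counted in both the PRRSV and the miR-30 list. The epithelial markers miR-183 (-5.00) and miR-182 (-2.85) passed over their list alone as well (2 of 3), lower at 60 h, beside the higher inflammation-induced miRNAs. miR-182 differed by -0.73 and miR-183 by -2.81 without the Landrace uninfected 9 h library. In that fit 0 of 3 epithelial, 0 of 10 miR-30, 0 of 10 miR-17-92 and 2 of 33 PRRSV miRNAs passed over the list alone. Other lists gained in the same fit. Over the list alone, 2 of 6 endothelial, fibroblast and muscle miRNAs passed (0 with all libraries), with 0 of 6 lower at 60 h. So did 2 of 7 stress miRNAs (1 with all libraries) and 1 of 5 lymphocyte miRNAs (0 with all libraries). Over the list alone, 8 of 33 PRRSV, 5 of 10 miR-30, 0 of 10 miR-17-92 and 2 of 3 epithelial miRNAs passed with unlisted values set to 1 rpm, and 3, 0, 0 and 0 with every value under 1 rpm taken as 0.

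In infected cells the smallest p of the joint test of the 3 times belonged to miR-143-3p, a miRNA of smooth muscle cells and fibroblasts, which did not pass. It was lower at 60 h than at 9 h in 3 of 4 breeds, with a log2 difference of -1.61. In the single contrast of 60 h with 9 h, 0 of 6 endothelial, fibroblast and muscle miRNAs, miR-143-3p among them, had an unadjusted p below 0.05 (edgeR). At 36 h, 2 of the 4 infected libraries did not list miR-143-3p. miR-146a-5p was higher at 60 h in 4 of 4 breeds by 2.20 on the log2 scale and miR-222 lower in 4 of 4 by -0.74, and neither passed. The differences were 1.68 for miR-574, -2.02 for miR-1285, -1.34 for miR-34c, -0.57 for miR-30c-5p, -0.53 for miR-155-5p, 0.45 for miR-21, -0.13 for miR-181a and -0.21 for miR-142-3p. edgeR called 0 of 186 miRNAs (smallest adjusted p 0.218), 7 had an unadjusted p below 0.05, and DESeq2 called 0.

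The breeds differed from each other in 75 of 186 miRNAs. miR-195, a member of the miR-15/16 family that restrains the cell cycle, was at 15.6 ± 2.35 rpm in Landrace, 4.30 ± 0.765 rpm in Meishan, 3.05 ± 1.20 rpm in Pietrain and 4.91 ± 1.17 rpm in QingPing (SD, n = 6 each), so that each Landrace library lay above every library of the other breeds (edgeR, adjusted p = 2.97e-05). miR-95 was at 47.1 ± 9.94 rpm in QingPing, 13.9 ± 5.24 rpm in Pietrain, 8.55 ± 4.81 rpm in Landrace and 5.01 ± 4.39 rpm in Meishan (SD, n = 6 each; adjusted p = 2.97e-05). miR-155-5p was at 157 ± 84.1 rpm in Pietrain and 26.5 ± 17.1 rpm in Meishan (SD, n = 6 each; adjusted p = 0.00609). The paired miRNAs miR-221-3p and miR-222, which come from 1 transcript, were highest in Landrace and lowest in Meishan by the fit. miR-221-3p was at 4059 ± 963 against 1572 ± 303 rpm and miR-222 at 2267 ± 643 against 622 ± 231 rpm (SD, n = 6 each, edgeR, adjusted p = 0.000186 and 0.000245). They parted in QingPing, where miR-221-3p was at 1599 ± 104 rpm, near Meishan, and miR-222 at 2242 ± 868 rpm, near Landrace (SD, n = 6 each).

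**Figure D3:**
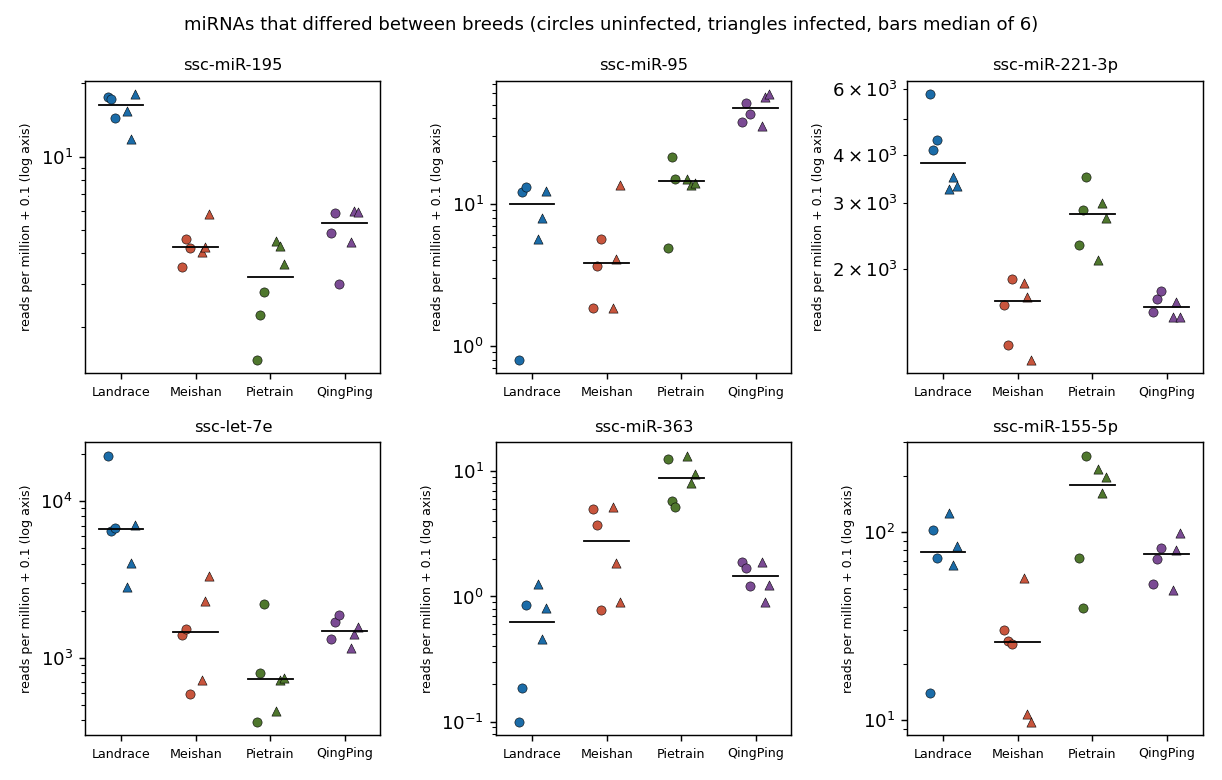
Each point is 1 library, in rpm after TMM scaling plus 0.1 on a log axis, for 6 miRNAs that differed between breeds; circles are uninfected, triangles infected cells, and bars are the median of the 6 libraries of a breed. For miR-195, all Landrace libraries lie at 11.7 rpm or more and all others at 5.85 rpm or less.

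Among the other miRNAs with the smallest p, let-7e was at 7785 ± 5998 rpm in Landrace and 886 ± 664 rpm in Pietrain (SD, n = 6 each; adjusted p = 0.000245). miR-503 was at 199 ± 88.8 rpm in Meishan and 40.9 ± 13.2 rpm in Pietrain, and miR-497 at 13.9 ± 1.79 rpm in Landrace and 4.57 ± 0.261 rpm in QingPing (SD, n = 6 each; adjusted p = 0.000245 and 0.000341). miR-363, of the miR-106a-363 cluster, was at 9.01 ± 3.38 rpm in Pietrain and 0.509 ± 0.442 rpm in Landrace (SD, n = 6 each; adjusted p = 0.000431). miR-296-3p was at 110 ± 34.9 rpm in Landrace and 20.1 ± 13.8 rpm in Meishan, and miR-125a, which restrains inflammatory activation of macrophages, at 20.2 ± 19.7 rpm and 3.36 ± 1.496 rpm in the same breeds (SD, n = 6 each; adjusted p = 0.000581 and 0.000788). miR-532-5p was at 646 ± 707 rpm in Meishan and 34.96 ± 14.1 rpm in Landrace (SD, n = 6 each; adjusted p = 0.000652). miR-206 passed as well (adjusted p = 0.000547), highest in Pietrain, but not with unlisted values set to 1 rpm (adjusted p = 0.0755). Single libraries raised some of these means: the Landrace uninfected 9 h library was at 19533 rpm for let-7e and 59.5 rpm for miR-125a, and the Meishan uninfected 60 h library at 2038 rpm for miR-532-5p. miR-30c-5p, reported to promote PRRSV infection, was at 32.1 ± 15.0 rpm in Pietrain and 10.3 ± 3.40 rpm in Meishan (SD, n = 6 each; adjusted p = 0.00164). Among the miRNAs to be named in every comparison, miR-181a (adjusted p = 0.0502), miR-146a-5p (adjusted p = 0.0858), miR-21 (adjusted p = 0.573) and miR-142-3p (adjusted p = 0.683) did not pass in edgeR. Without the 4 libraries that stood apart miR-181a (adjusted p = 0.0322), miR-146a-5p (0.00422) and miR-21 (6.57e-05) passed, and miR-142-3p did not (0.532). Across 25 alternatives these passed in 7, 9, 2 and 0, in the same order.

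By list, 10 of 16 inflammation-induced miRNAs, 11 of 33 miRNAs with a reported action on PRRSV, 7 of 13 myeloid and pan-leukocyte miRNAs, 2 of 9 of the let-7 family, 4 of 10 of the miR-17-92 clusters and 6 of 10 of the miR-30 family differed between breeds. So did 5 of 8 of the miR-15/16 family (miR-195, miR-503, miR-497 and miR-424-5p among them), 2 of 4 of the miR-181 family, 0 of 3 of the miR-29 family and 3 of 7 hypoxia, p53 and stress miRNAs, including miR-107 at 12340 ± 3934 rpm in Meishan and 4870 ± 272 rpm in QingPing (SD, n = 6 each). Of the markers of other cells, 1 of 3 epithelial, 2 of 4 erythrocyte, 3 of 5 lymphocyte and 4 of 6 endothelial, fibroblast and muscle miRNAs passed. Over all tested miRNAs 75 of 186 passed, and no set test was run on breed, so these counts do not single out a list. Adjusted over the list alone, the counts were 11, 7, 7, 2, 4 and 6 for the lists of the first sentence in that order, 5 for miR-15/16, 3 for miR-181, 0 for miR-29, 4 for the stress list, and 1, 2, 4 and 4 for the markers of other cells. miR-424-5p was at 112 ± 18.7 rpm in QingPing and 17.9 ± 11.5 rpm in Pietrain (SD, n = 6 each; adjusted p = 0.00166).

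Between single pairs of breeds edgeR called 46 miRNAs for Meishan against Pietrain, 40 for Landrace against Pietrain, 32 for Pietrain against QingPing, 25 for Landrace against Meishan, 24 for Meishan against QingPing and 22 for Landrace against QingPing. The share of these that was higher in one breed moved with the scaling. For Landrace against Meishan 20 were higher and 5 lower in Landrace under TMM, 13 and 20 under upper quartile scaling, 12 and 17 under DESeq2 size factors, and 16 and 3 under scaling by the clean reads alone. For Meishan against Pietrain 12 were higher and 34 lower in Meishan under TMM, 12 and 11 under upper quartile scaling, 12 and 15 under DESeq2 size factors, and 9 and 41 under scaling by the clean reads alone. The splits for Landrace against QingPing were 15 and 7, 6 and 6, and 9 and 8 in the same order, and for Meishan against QingPing 7 and 17, 9 and 8, and 7 and 9. For Landrace against Pietrain they were 21 and 19, 19 and 22, and 20 and 21, and scaling by the clean reads alone gave 12 and 23. For Pietrain against QingPing they were 20 and 12, 20 and 11, and 15 and 12, and scaling by the clean reads alone gave 11 and 14. Scaling by the clean reads alone gave 1 and 13 for Landrace against QingPing and 1 and 29 for Meishan against QingPing. TMM on the sum of the tested miRNA reads gave 14 and 14 for Landrace against Meishan and 12 and 18 for Meishan against Pietrain. It gave 7 and 8 for Landrace against QingPing and 5 and 15 for Meishan against QingPing. For Landrace against Pietrain it gave 20 and 20, and for Pietrain against QingPing 15 and 15.

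The count for breed was 75 in edgeR, with 92 at an unadjusted p below 0.05, and 87 in DESeq2. Without the 4 libraries that stood apart it was 133, of which 71 were among the 75. With unlisted values set to 1 rpm it was 64, and with every value under 1 rpm taken as 0 it was 42, all among the 75. miR-195, miR-95, miR-221-3p, miR-503, miR-222, let-7e, miR-497, miR-363, miR-296-3p, miR-532-5p, miR-125a and miR-30c-5p each passed in 25 of 25 alternatives, with the highest adjusted p at 0.0408 for miR-30c-5p. miR-155-5p passed in 23 of 25 (highest adjusted p 0.0588), miR-107 in 24 of 25 (0.0836) and miR-206 in 22 of 23 (0.0755). With 1 library per breed, infection state and time, the differences measure libraries of a breed in this culture, and the labels do not say how many animals stood behind them.

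The last comparison asked whether PRRSV infection acted differently in the breeds. The smallest p-values belonged to miR-30c-3p, miR-130a, miR-532-5p, miR-296-3p and miR-16, a cell cycle regulator abundant in blood cells, and none passed. edgeR called 0 of 186 miRNAs (smallest adjusted p 0.857), 8 had an unadjusted p below 0.05, and DESeq2 called 0. Within each breed, over the 3 times, edgeR called 0 miRNAs for infection in Landrace, Meishan, Pietrain and QingPing, with 20, 24, 18 and 1 at an unadjusted p below 0.05. The libraries that stood apart were of Landrace, Meishan and Pietrain, and none was of QingPing. These counts therefore do not rank the breeds by their response to PRRSV. On simulated data the test for a difference between breeds recovered 0.8% of 4-fold changes, so that differences of this size were not detectable in this design.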

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

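The tests of the Landrace uninfected 9 h library, and the test of whether run 1 of the Meishan uninfected 60 h library resembled the other Meishan libraries, were chosen after the results were seen, as were the groups tested for single libraries that lay far from the others and the alternatives that leave out libraries. The gap between a library and its nearest neighbour was divided by the range of its group. By this gap ratio, 20 of 78 groups of 4 or 6 libraries held a library beyond Dixon's 95% limit. Chance gives about 1 in 20 groups only for normally distributed values, and these values were not log-transformed. A group in which a single library had reads has a ratio of 1.0 by construction, as for miR-206 in infected cells at 60 h. Many of the groups also share the same libraries. The count of 20 of 78 therefore does not show more outlying libraries than chance would give.

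The Landrace uninfected 9 h library lay far from the other uninfected 9 h libraries in miR-31 (gap ratio 0.996), miR-92b-5p (0.990), miR-100 (0.973) and miR-139-5p (0.932). Low depth was excluded, since the library held 11.28 M miRNA reads, above the median of the 24 libraries. The median log2 ratio of 13 myeloid and pan-leukocyte miRNAs to the other Landrace libraries was -1.91, with miR-142-5p at -8.94 and miR-142-3p at -6.07, while miR-23a was at -0.24, so RNA of other cells in place of macrophage RNA is a candidate explanation that these values leave open. miR-24-3p, miR-23a and miR-503 of that list are also made by many other cell types, and no sort of the lavage cells is described in the sources used here. A biological difference of the Landrace cells at this time cannot be separated from it, because the design has 1 such library.

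The Meishan uninfected 60 h library was deposited with values of 2 runs that differ. Depth was excluded as the whole cause, since run 2 thinned to the miRNA reads of run 1 kept a correlation of 0.999 with the whole of run 2, while the runs correlated at 0.884. Run 1 had a median correlation of 0.866 with the other 5 Meishan libraries, below the lowest between any pair of those 5 (0.906), and run 2 had 0.962; let-7f was at 16003 rpm in run 1, 279831 rpm in run 2 and 223002 ± 65458 rpm (SD, n = 5) in the other Meishan libraries. RNA of another kind in run 1 may account for this, and whether it was another sample or a degraded one was not tested. Run 2, which the comparisons did not use, held 72.1% miRNA reads in the uninfected 60 h library and 26.9% in the infected 9 h library, where the share in run 1 was 27.5%.

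miR-206 and miR-1 were far higher in the Pietrain uninfected 60 h library than in the other uninfected 60 h libraries (gap ratios 0.943 and 0.956). The median log2 ratio of the other 3 muscle miRNAs to the other Pietrain libraries was 0.22, with miR-499-5p at 65.3 rpm against 56.1 rpm before TMM scaling and miR-1 at 602 rpm against 11.3 rpm. miR-133a-3p was not listed in this library and may lie anywhere up to about 1 rpm, so the median depends on how it is read, and RNA of muscle cells was left open. The test of infection called miR-206 with unlisted values taken as 0 and listed values under 1 rpm kept. The call ended with unlisted values set to 1 rpm, and also with every value under 1 rpm, listed or not, taken as 0. The 8 ways to part each breed's pair at 60 h are too few for a share under 0.05 (2 of 8 as large, the real split 1 miRNA, the highest other 1). Among all 35 splits of these 8 libraries, 6 called as many and the highest called 3.

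The share of miRNA reads had 1 library apart in uninfected cells at 60 h (0.848, Meishan at 42.2%) and in infected cells at 60 h (0.83, Landrace at 74.3%). The QingPing library was apart in miR-92b-5p of infected cells at 9 h (0.839, at 15.8 rpm). The Pietrain library was apart in miR-206 of infected cells at 9 h (0.969, at 7.10 rpm) and at 60 h (1.0, at 0.466 rpm), in miR-218-3p of uninfected cells at 36 h (1.0, at 0.648 rpm) and in miR-139-5p of uninfected cells at 60 h (1.0, at 0.383 rpm), the other libraries being at 0 or not listed in the last 3 groups. Within Landrace the uninfected 9 h library was apart in let-7e (0.746, at 19533 rpm) and miR-125a (0.771, at 59.5 rpm). Within Meishan the infected 60 h library was apart in miR-95 (0.677, at 13.5 rpm) and the uninfected 60 h library in miR-532-5p (0.723, at 2038 rpm). Within Pietrain the uninfected 60 h library was apart in let-7e (0.772, at 2196 rpm) and the uninfected 9 h library in miR-30c-5p (0.714, at 61.8 rpm). Within QingPing 1 library was apart in miR-497 (0.691, at 5.08 rpm).

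Random splits of the libraries were set against the other counts. For breed, 1 of 100 splits, the real one, called as many as 75 miRNAs and the highest other called 15. A random grouping of single libraries was therefore excluded. The splits exchanged libraries between breeds as if they were independent, while libraries of 1 breed deviated together (median correlation 0.47). If the libraries of a breed share animals or a pool, these splits cannot tell breed from chance differences between animals or pools. For time in uninfected cells 28 of 100 splits called at least 2 miRNAs and the highest other called 24, so chance was not excluded. How the split with 24 calls grouped the libraries was not examined. Where the real count was 0, every split was as large: 100 of 100 for infection over all times (highest other 0), for infection by time (highest other 1), for time in infected cells (highest other 0) and for breed by infection (highest other 1). At 9 h and at 36 h, 8 of 8 splits that part each breed's pair gave as many as the real 0 (highest other 0 at both times), and 8 are too few for a share under 0.05; among all 35 splits at 9 h the highest called 6.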

How the results depend on the processing

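The alternatives chosen after the data were seen were those that leave out single libraries or the 4 that stood apart, and run 2. The others were scaling by the clean reads alone, the robust option of edgeR, and the 2 other readings of values under 1 rpm. A further one was TMM on the sum of the tested miRNA reads, called the sum of miRNA reads below, which still holds TMM factors. Replicates 1 to 4 are Meishan, QingPing, Landrace and Pietrain, and in the leave-one-out fits of the breed tests 1 infection and time group was left out. The counts of passing miRNAs moved as follows, and the cause was not tested. With a filter of 100 reads, or with only miRNAs listed in every library, infection at 60 h gave 0 and time in uninfected cells 0, as miR-206 and miR-139-5p were then not tested. DESeq2 gave 13 for infection over all times, 17 at 9 h, 9 at 60 h and 25 for time in uninfected cells. Without the breed term infection at 60 h gave 0 and time in uninfected cells 14; the uninfected libraries alone gave 0. Without 1 replicate the range was 0 to 1 at 60 h, 0 to 1 for infection by time, and 0 to 3 for time in uninfected cells, and leave-one-out gave 37 to 105 for breed. Without the 4 libraries that stood apart infection at 60 h gave 2 (miR-206, and miR-1 with adjusted p = 0.00478), infection by time 1 (miR-206), time in uninfected cells 5 (miR-1, miR-139-5p, miR-206, miR-296-3p and miR-574), breed 133 and breed by infection 1 (miR-10a-5p, adjusted p = 0.0425). Without the Landrace uninfected 9 h library infection by time gave 1, and without the Pietrain uninfected 9 h library time in uninfected cells gave 8. With unlisted values set to 1 rpm, and with every value under 1 rpm taken as 0, infection at 60 h gave 0 and time in uninfected cells 0, and taking values under 1 rpm as 0 gave 42 for breed. With estimated correlations 0 in place of 2 set tests passed. Of 3003 values of named miRNAs under alternatives, 2727 stayed on the same side of the threshold with the same direction, 153 no longer passed, 41 newly passed and 82 changed direction, all 82 for miRNAs that had not passed. The pseudocount and limma alternatives do not apply to counts and were not run.

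The log2 differences that changed direction were these. For breed by infection, a joint test of all breeds without a single direction, the value is the infection effect of Landrace against the mean of the breeds. Without the 4 libraries that stood apart, infection over all times gave -0.216 for miR-155-5p; infection at 9 h gave 0.141 for miR-100, -0.082 for miR-155-5p, -0.052 for miR-21, 0.11 for miR-30c-5p and -0.097 for miR-146a-5p. The same fit gave for infection by time -0.46 for miR-30c-5p, 0.123 for miR-21, 0.287 for miR-181a and 0.332 for miR-146a-5p, for time in uninfected cells -0.128 and in infected cells 0.159 for miR-181a, and for breed by infection -0.417 for miR-30c-5p. Without the Landrace uninfected 9 h library the values were -0.031 for miR-30c-5p and -0.072 for miR-142-3p at 36 h, -0.056 for miR-21 at 60 h, 0.216 for miR-181a and 0.459 for miR-146a-5p in infection by time, and -0.458 for miR-181a in time of uninfected cells. Without the Pietrain uninfected 9 h library they were 0.272 for miR-181a at 9 h and -0.328 for miR-21 at 60 h. Without the Pietrain uninfected 60 h library they were 0.053 for miR-155-5p at 36 h, and 0.037 for miR-142-3p and -0.18 for miR-21 at 60 h. Without the Meishan uninfected 60 h library miR-181a was at 0.032 in infection by time and -0.207 in time of uninfected cells. With run 2, miR-155-5p was at 0.047 at 36 h and miR-30c-5p at -0.109 in infection by time.

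With unlisted values set to 1 rpm the values were -1.388 for miR-218-3p, -0.264 for miR-139-5p, -0.852 for miR-19a, -0.221 for miR-4332 and 0.002 for miR-155-5p at 36 h, and -1.045 for miR-184 and -0.346 for miR-24-2-5p at 60 h. With every value under 1 rpm taken as 0 they were 0.009 for miR-155-5p at 36 h and -0.058 for miR-21 at 60 h. For miR-155-5p at 36 h upper quartile scaling gave 0.044, no filter 0.064, no breed term 0.403, the time fitted alone 0.045, clean reads alone 0.094 and the sum of miRNA reads 0.018. For miR-21 at 60 h DESeq2 size factors and the DESeq2 test gave -0.214, no filter -0.163, the filter of 100 reads -0.324, miRNAs listed in every library -0.309, identical miRNAs counted once -0.287, the time fitted alone -0.275, clean reads alone -0.16 and the sum of miRNA reads -0.127. For miR-181a the time fitted alone gave 0.056 at 9 h, no breed term 0.123 in infection by time and -0.198 in time of uninfected cells, upper quartile scaling -0.007 in time of uninfected cells, and clean reads alone 0.106 in time of infected cells, where miR-142-3p was at 0.025. No breed term gave 0.005 for miR-30c-5p at 60 h and 0.611 for miR-146a-5p in infection by time.

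Without 1 replicate, the ranges were -0.067 to 0.465 for miR-21 over all times; -0.792 to 0.213 for miR-181a at 9 h; at 36 h -0.032 to 4.495 for miR-4332, -0.493 to 0.001 for miR-181a, -0.013 to 0.228 for miR-30c-5p and -0.464 to 0.349 for miR-155-5p. At 60 h they were -0.402 to 0.032 for miR-30c-5p and -0.46 to 0.183 for miR-21. In infection by time they were -0.053 to 0.851 for miR-30c-5p, -0.973 to 0.22 for miR-181a and -0.996 to 0.383 for miR-146a-5p. In time they were -0.206 to 1.046 for miR-181a in uninfected cells, and in infected cells -0.818 to 0.264 for miR-181a and -0.478 to 0.055 for miR-142-3p. In breed by infection leave-one-out gave, for Landrace against the mean of the breeds, -0.382 to 2.543 for miR-142-3p and -0.138 to 0.849 for miR-30c-5p.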

Other observations

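The counts of the authors' tables and the library values in this part were chosen after the data were seen. The let-7 family, which is abundant in differentiated cells, was abundant in these macrophages as well, with let-7f and let-7a at the head of most libraries. The most abundant miRNA of a library, whichever it was, held between 18.5% and 41.2% of its miRNA reads. In the Meishan uninfected 60 h library miR-320 was at 93354 rpm before TMM scaling, against 17515 ± 7119 rpm (SD, n = 5) in the other Meishan libraries, and miR-1307 at 1396 rpm against 56.0 ± 34.5 rpm (SD, n = 5). In the other run of that library miR-320 was at 15464 rpm and miR-1307 at 138 rpm. These 2 miRNAs were among the 5 with the smallest p for infection over all times.

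The authors' tables compare single libraries, so their counts carry no replicate error; counted here are miRNAs with a deposited log2 fold change of at least 1 in size and a deposited p below 0.01. At 9 h the deposited tables listed 53 miRNAs higher and 94 lower in infected than in uninfected Landrace cells, 73 higher and 42 lower in Pietrain, 13 higher and 35 lower in Meishan, and 4 higher and 2 lower in QingPing. At 36 h the counts were 12 and 2 in Landrace, 5 and 16 in Pietrain, 26 and 17 in Meishan, and 7 and 2 in QingPing. At 60 h they were 0 and 12 in Landrace, 14 and 23 in Pietrain, 48 and 36 in Meishan, and 4 and 15 in QingPing. The Landrace, Pietrain and Meishan counts at 9 h each involve a library that stood apart in its miRNA share or its correlation with the others. The Meishan counts at 60 h cover 169 miRNAs, as many as run 2 of the uninfected 60 h library listed. The comparisons of that library with other breeds held run 1. These 60 h counts therefore rest on run 2, which held 72.1% miRNA reads and had a median correlation of 0.962 with the other 5 Meishan libraries.

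The miRNA shares of the QingPing libraries lay between 62.6% and 69.2%. The correlation of their deviations from the group means was above 0.1 for 15 of 15 pairs, with a median of 0.50 against 0.53 in Pietrain. In Landrace 10 of 15 pairs, in Meishan 12 of 15 and in Pietrain 14 of 15 were above 0.1.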
